A study of Mus musculus with 6 samples.

How the data were processed

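Gene expression was measured by mRNA sequencing in 6 libraries of mouse embryonic stem cells in 3 groups of 2. Per the labels, KO cells were DGCR8-null and not transfected. The wt and E518K cells carried a transposon vector for Flag-tagged DGCR8, either wild type or with the E518K substitution. All cells received 300 ng/mL doxycycline for 48 h and were grown without feeders in medium with LIF and inhibitors of GSK3 and MEK. Per the labels, RNA was selected with oligo-dT, primed with hexamers and sequenced in paired ends on a BGISEQ-500 instrument.

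The deposited count table held raw whole-number counts per gene symbol, 1 column per library, with no normalization by the authors. The deposited TPM table held the same counts divided by 1 length per gene and scaled to the same sum in each library by the authors. STAR, bedtools and the mouse build GRCm38.p6 are named in the submitters' processing notes, and their versions, roles and settings are not given in the sources used here. The counting rule was therefore examined in the values. The length implied by count and TPM followed the genomic span of the gene within 5% for 98.1% of 19094 genes, and the exonic length for 3.58%. In 271 pairs in which a gene lay inside another on the same strand, the outer count was at least the inner count in 100% of pairs, and on opposite strands in 99.4% of 170 pairs. Counts therefore behaved as reads over the whole span of a gene, introns included and without regard to strand. Of the matched genes, 3539 (17.9%) overlapped another gene of the table and can share its reads.

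The table held 21978 entries, with 14 duplicated symbols kept as separate genes. GENCODE M21 on GRCm38 gave coordinates for 19795 symbols, 19556 by symbol and 239 through a RefSeq synonym. A further 24 symbols lay at several loci and 2131 were not matched. No column of sample values was left unused.

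Library totals ranged from 73642784 to 75121971, so depth differed little between groups. Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM factors, the default expression filter with a minimum count of 10, and quasi-likelihood F tests with robust estimation. All 6 libraries entered 1 fit with group as the only term, which left 3 residual degrees of freedom and a common biological coefficient of variation of 11.9%. The filter kept 16498 genes. Adjusted p values follow Benjamini and Hochberg, with a threshold of 0.05. Values in CPM are counts scaled to library size and were computed here with the TMM factors. An error of a log2 fold change is its standard error from that fit, and n is 2 libraries per group unless stated.

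The design text speaks of independent clones in each condition, whereas both KO titles carry clone number 261. The p values therefore measure the spread between these libraries, which for KO can be technical. Because the fit pools the spread over all groups, the errors and p values of E518K against wt also draw on the KO libraries. With only the 4 libraries compared, that comparison had 1999 calls, against 3917 in the pooled fit. Replicate libraries differed by more than sampling noise in each group, with a chi-square per degree of freedom of 3.55 for KO, 51.4 for wt and 21.6 for E518K over genes with at least 10 reads.

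Before the data were examined, 36 gene lists, 15 miRNA seed families, the comparisons, the tests, the named-gene rule and most alternatives were fixed. The summing of the KO libraries, the restriction to genes that overlap no other gene, the adjustment for UTR composition, the fit of all seed families together and the simulation with the spread of each group were added after seeing the data. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and 34 lists had at least 5 tested members. Adjustment ran over the 102 tests of lists and comparisons. Camera with an estimated correlation was run beside it, as was fry, which tests a list against no change and not against other genes; ranges over the alternatives leave fry out. The list of noncoding miRNA host transcripts had 0 of 22 members in the table and was not tested. Seed families were tested in the same way over 45 tests, comparing genes with a 7mer-m8 site in the longest annotated 3′ UTR with the other genes among 14959 that had a UTR of at least 20 bases.

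Named genes followed a rule. It took the miRNA machinery list, and for each comparison the 8 largest increases and the 8 largest decreases among called genes with an average log2 CPM of at least 1 and no overlap between libraries, passing over predicted models. It also took up to 4 members of each list with the smallest p, the members of lists with 12 or fewer tested genes, and list members called in opposite directions against wt in KO and E518K. Outside this rule, Myadm, Trmt2a and Aktip are named for their position beside or over another named gene.

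The position of E518K between wt and KO was computed from the mean log2 CPM of a gene set minus that of the other tested genes. Because KO and E518K were both compared with the same wt libraries, 20 simulations of unchanged groups sharing those libraries were run. A further 20 used the trended dispersion of each group from its 2 libraries, where the common biological coefficient of variation was 2.61% in KO, 20.5% in wt and 9.19% in E518K. The pipeline was tested on simulated negative binomial counts with the mean level of each gene, the library sizes and the trended dispersion of the real data, a smaller spread than that of the most variable genes. Of genes changed 1.5-fold, 2-fold and 4-fold, the test found 77.6%, 89.6% and 100% for KO against wt. For E518K against wt it found 55.2%, 79.1% and 100%, and for E518K against KO 73.1%, 88.1% and 95.5%. Of 16278 unchanged genes it called 14, 8 and 6 in the same order of comparisons. This simulation gave all groups 1 spread, whereas the real groups differed in spread as given above. Its rates need not hold for the single comparisons of the real data.

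Alternatives were RLE and upper-quartile factors, other filters, the 4 libraries of a comparison alone, a 2-fold minimum, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with a mean TPM of at least 1, other site definitions, and leaving out each library in turn. Annotation and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.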

Results

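Poly(A)-selected RNA was sequenced from 6 cultures of mouse embryonic stem cells that differed in DGCR8, the RNA-binding partner of Drosha in the complex that releases precursor miRNAs from primary transcripts. The groups were DGCR8-null cells (KO, libraries 1 and 3), cells with an induced wild-type protein (wt, clones 12 and 16) and cells with an induced protein carrying the E518K substitution (E518K, clones 8 and 15). The series title links this substitution to Wilms tumours, so the comparisons ask what differs without DGCR8 and between cells with either protein. The genotype labels read wt/wt and E518K/E518K while the transfection labels name a vector, so whether these cells derive from the KO line is not given in the sources used here. Totals ranged from 73642784 to 75121971 counts per library. The first principal component held 67.3% of the variance and placed KO at -72.9 and -73.3, E518K at 9.57 and 5.55, and wt at 79.9 and 51.2. The second held 15.4% and set E518K (-37.1 and -39.0) apart from KO (18.0 and 15.7) and wt (30.1 and 12.3), and the third held 9.85% and separated the wt clones (-29.7 and 43.2).

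Dgcr8 itself (chromosome 16, 18253948 to 18289246, minus strand, GRCm38) was measured first as a check of the labels. Its level was 40.0 and 37.1 CPM in the KO libraries, 195.5 and 992.4 CPM in wt clones 12 and 16, and 820.6 and 420.2 CPM in E518K clones 8 and 15. The log2 fold change was -3.95 ± 0.73 (SE) in KO against wt (edgeR adjusted p = 0.00316) and 4.01 ± 0.73 in E518K against KO (adjusted p = 0.00455). E518K and wt differed by 0.06 ± 0.64 (adjusted p = 0.953), and without 1 library at a time this value ranged from -0.67 to 1.67. The call in KO against wt was lost without KO library 1, KO library 3 or wt clone 16 (-4.00, -3.89 and -2.35; adjusted p = 0.0586, 0.0625 and 0.0535), and that in E518K against KO without KO library 1 or 3 (4.07 and 3.96; adjusted p = 0.0829 and 0.0862). Both calls were also lost with no low-count filter (adjusted p = 0.0602 and 0.0742) and with the KO libraries summed, chosen after seeing the data (adjusted p = 0.0568 and 0.0802). The span overlaps that of Trmt2a, so some counts in KO can belong to Trmt2a, and the position of the deletion is not given in the sources used here.

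**Figure D1:**
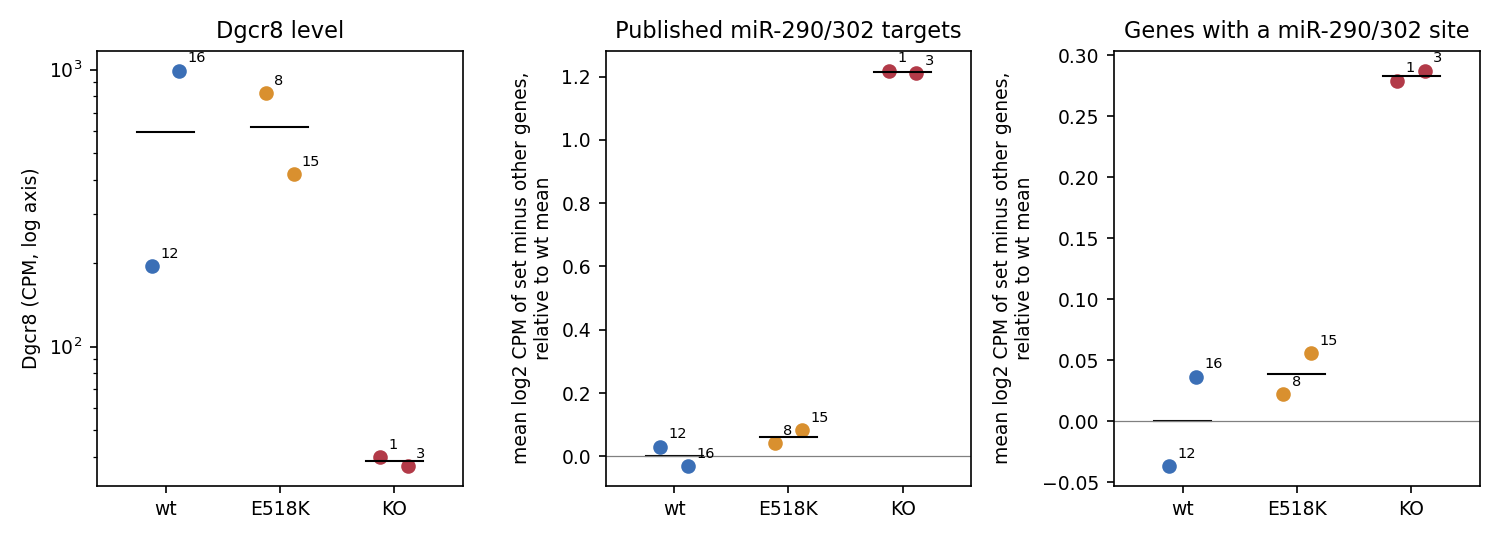
Dgcr8 level in CPM on a log axis (left) and the mean log2 CPM of published miR-290 targets (centre) and of genes with a miR-290 site (right) minus that of the other tested genes, relative to the wt mean. Points are single libraries with their numbers and lines are group means; the KO libraries stand at 1.22 and 1.21 for the published targets and the E518K libraries at 0.04 and 0.08.

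In KO, expression rose for genes that earlier work had named as targets of the miR-290 family, abundant in mouse embryonic stem cells and sharing its seed with miR-302. Irf2, a transcription factor of the interferon response, rose by 5.42 ± 0.27 (SE) on the log2 scale, from 0.164 ± 0.036 to 7.09 ± 0.02 CPM (SD, n = 2). Tgfbr2, a receptor for TGF-beta, rose by 3.29 ± 0.23 and Lats2, a kinase of the Hippo pathway, by 2.85 ± 0.10. Rbl2, a pocket protein of the cell cycle, rose by 2.05 ± 0.12 and Casp2 by 1.37 ± 0.09. Of 19 tested members of this list, 15 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.62e-05, and adjusted p = 0.705 with an estimated correlation). Rbl2 overlaps Aktip and can share its reads.

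Targets of p53 also rose in KO. The cell-cycle inhibitor Cdkn1a, which the list of miR-290 targets holds too, rose by 1.72 ± 0.13, Btg2 by 2.08 ± 0.12 and the apoptosis gene Pmaip1 by 0.76 ± 0.06. Of 21 members, 15 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.00125, and adjusted p = 0.851 with an estimated correlation). Genes of interferon signalling and RNA sensing showed a like direction, with Ifi35 higher by 2.10 ± 0.12, Irf9 by 1.85 ± 0.09 and Ifitm3 by 1.03 ± 0.06. In that list 13 of 24 members rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.705 with an estimated correlation). Zbp1, a sensor of nucleic acids outside the lists, had the largest increase among genes named in KO against wt at 5.78 ± 0.29. Of 8 tested blood and immune markers, Cd3e rose by 1.92 ± 0.18, whereas Itgam and Cd79a fell, and the abundant Laptm5 stood at -0.11 ± 0.06 (adjusted p = 0.141).

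Transcripts encoded in the mitochondrial genome rose together in KO. All 13 passed the test, also when adjusted over the list alone, among them mt-Nd1 and mt-Co3, each at 0.73 ± 0.06, and mt-Atp6 at 0.66 ± 0.05 (adjusted p = 6.29e-04, and adjusted p = 0.705 with an estimated correlation). Their share of counts was 5.00% and 4.97% in KO, 3.24% and 3.23% in wt, and 3.80% and 3.56% in E518K.

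Genes of hypoxia and glycolysis fell in KO. The glycolytic enzymes Aldoa, Pfkp and Pkm fell (-2.35 ± 0.10, -1.73 ± 0.07 and -1.52 ± 0.07), and the mitophagy receptor Bnip3 fell by 3.08 ± 0.16. Of 20 members, 17 fell and 1 rose, also when adjusted over the list alone (adjusted p = 6.92e-07, and adjusted p = 0.851 with an estimated correlation). Slc16a3, the lactate exporter, lies outside the list and fell by 5.67 ± 0.27. In the list of the integrated and unfolded protein stress responses, 13 of 20 members fell and 4 rose, also when adjusted over the list alone, with Chac1 at -4.17 ± 0.14 and the transcription factor gene Atf4 at -1.15 ± 0.07 (adjusted p = 0.00965, and adjusted p = 0.705 with an estimated correlation).

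Cholesterol and lipid synthesis genes fell as well, including the desaturases Scd1 and Scd2, with changes of -1.84 ± 0.09 and -1.12 ± 0.07. Of 20 members, 13 fell and 2 rose, against 14 and 2 adjusted over the list alone (adjusted p = 0.0127, and adjusted p = 0.851 with an estimated correlation). Ribosomal protein genes such as Rplp0 and Rpl8 fell (-0.99 ± 0.07 and -0.93 ± 0.06). In that list 17 of 24 members fell and 3 rose, against 18 and 3 adjusted over the list alone (adjusted p = 0.00382, and adjusted p = 0.851 with an estimated correlation). The stress list lost its call when genes that overlap another gene were removed (adjusted p = 0.0527, with a range of 0.00779 to 0.705 over the alternatives), an alternative chosen after seeing the data.

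**Figure D2:**
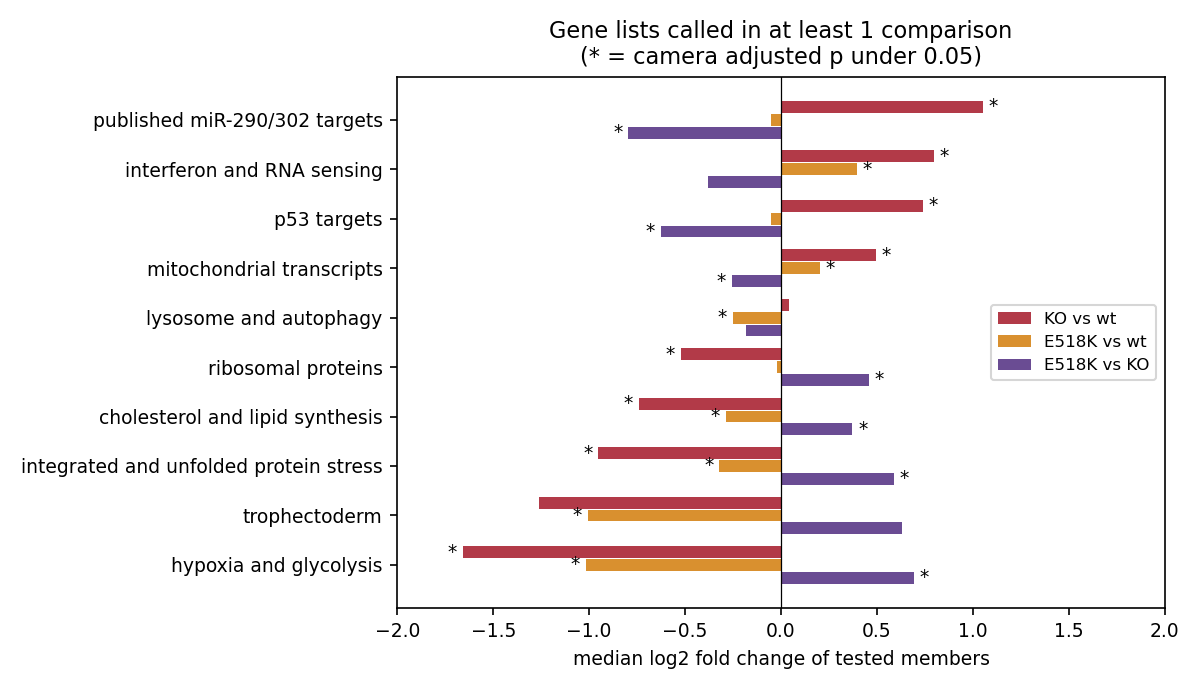
Median log2 fold change over the tested members of each gene list that passed the test in at least 1 comparison. Bars are coloured by comparison and an asterisk marks a camera adjusted p under 0.05; the glycolysis list stands at -1.66 in KO against wt, -1.02 in E518K against wt and 0.69 in E518K against KO.

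Among single genes, Lin28a, an RNA-binding protein that blocks let-7 maturation, fell by 6.37 ± 0.24 in KO, from 99.5 ± 24.2 to 1.20 ± 0.02 CPM (SD, n = 2). Its paralog Lin28b rose by 1.93 ± 0.33 (adjusted p = 0.00235). Dnmt3l, a cofactor of de novo DNA methylation, fell by 5.42 ± 0.23, and Aire, which overlaps it, fell by 7.51 ± 0.47, so the 2 values can share reads. Of the Argonaute and GW182 proteins that carry out miRNA silencing, Ago1 rose by 1.09 ± 0.08, Ago3 by 0.73 ± 0.14, Tnrc6a by 1.51 ± 0.10 and Tnrc6b by 1.27 ± 0.14. Over the whole miRNA machinery list 8 of 17 members rose and 5 fell, against 8 and 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.455). Its median of 0.18 and the direction of its test were higher, whereas its mean was -0.18.

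Counts over the span of Nlrp12 (chromosome 7, 3218784 to 3249740, minus strand) rose by 4.85 ± 0.09 in KO, from 13.4 ± 0.83 to 386.2 ± 25 CPM (SD, n = 2). This span holds the annotated hairpins of miR-291a to miR-295, 6 of them on the strand opposite to Nlrp12, and counting did not separate strands. Fbxo32, a ubiquitin ligase subunit, rose by 4.65 ± 0.22 and the homeobox gene Evx1 by 5.20 ± 0.33. Igfbp4 fell by 4.90 ± 0.28.

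In total 9429 of 16498 genes passed the edgeR test between KO and wt, 4526 higher and 4903 lower in KO, and 3560 of them changed at least 2-fold. The libraries of the groups did not overlap for 81.7% of genes. The 33.3% that chance gives holds for independent libraries with a like spread and is no reference here. Both KO titles carry the same clone number, and the common biological coefficient of variation was 2.61% in KO and 20.5% in wt. Without KO library 1 the count was 6196 and without KO library 3 it was 6084. Of 80 named genes that passed, 8 lost the call without KO library 1, 10 without KO library 3, 3 without wt clone 16 and 2 without either E518K clone.

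E518K cells differed from wt cells in fewer genes. The published miR-290 targets mostly did not pass. Of 19 members, 3 were higher and 1 lower, against 4 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.934), with a median of -0.05, a mean of 0.04 and a test direction of lower. Lats2 rose by 0.74 ± 0.10 and Irf2 by 1.74 ± 0.29, whereas Cdkn1a stood at -0.37 ± 0.12 (adjusted p = 0.0663), Tgfbr2 at -0.79 ± 0.26 (adjusted p = 0.0633) and Rbl2 at -0.33 ± 0.12 (adjusted p = 0.0782). Among p53 targets 1 rose (Perp) and 1 fell (Gdf15), against 0 and 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.903). Its median was -0.05, whereas its mean of 0.05 and the direction of its test were higher.

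Nlrp12 span counts had the largest increase named in E518K against wt at 3.87 ± 0.08, reaching 195.8 ± 6.45 CPM (SD, n = 2). Fbxo32 rose by 3.70 ± 0.22 and Evx1 by 3.35 ± 0.32, the same direction as in KO. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 3.07 ± 0.18. The lymphocyte genes Cd3d and Cd3e rose by 3.02 ± 0.41 and 1.90 ± 0.18, the Fc receptor gene Fcgr2b by 2.87 ± 0.27 and Gpr83 by 3.06 ± 0.24. Igfbp4, Tgfbi and the glycine decarboxylase gene Gldc fell (-3.20 ± 0.25, -3.02 ± 0.27 and -2.65 ± 0.28).

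Hypoxia and glycolysis genes were lower in E518K than in wt. Vegfa and Egln3, hypoxia-responsive genes outside glycolysis itself, stood at -2.41 ± 0.17 and -1.10 ± 0.09, and the glycolytic Pfkp and Pgk1 at -1.03 ± 0.07 and -1.01 ± 0.10. Of 20 members, 17 fell and 0 rose, against 18 and 0 adjusted over the list alone (adjusted p = 5.96e-08, and adjusted p = 0.851 with an estimated correlation). Interferon and RNA sensing genes were higher, with Oas1a at 1.30 ± 0.18 and Ifitm3 at 0.76 ± 0.06. In that list 7 of 24 members rose and 3 fell, against 10 and 3 adjusted over the list alone (adjusted p = 0.00965, and adjusted p = 0.705 with an estimated correlation). Of the blood and immune markers, Cd3e rose as given above, Cd79a fell by 0.90 (adjusted p = 0.0427) and the most abundant, Laptm5, stood at -0.07 ± 0.06 (adjusted p = 0.373).

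Trophectoderm markers fell in E518K, among them Ascl2 (-1.10 ± 0.18) and Krt18 (-1.27 ± 0.23). Of 13 members, 7 fell and 1 rose, against 9 and 2 adjusted over the list alone (adjusted p = 0.0363, and adjusted p = 0.851 with an estimated correlation). The call was lost without wt clone 12 (adjusted p = 0.188) and without wt clone 16 (adjusted p = 0.0944), with a range of 0.0203 to 0.851 over the alternatives. In the lysosome and autophagy list Ctsl fell by 0.88 ± 0.08 and Psap fell by 0.65 ± 0.09. There 10 of 20 members fell and 2 rose, against 12 and 2 adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.851 with an estimated correlation). That call was lost without wt clone 12 (adjusted p = 0.101) and with genes that overlap no other gene (adjusted p = 0.175), with a range of 0.00451 to 0.851 over the alternatives. Tested with fry against no change, and not against other genes, the list did not pass (adjusted p = 0.0688).

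Stress response genes fell in 10 of 20 cases and rose in 2, against 11 and 2 adjusted over the list alone, with Chac1 at -1.40 ± 0.12 and the chaperone gene Hspa5 higher by 0.60 ± 0.06 (adjusted p = 0.0262, and adjusted p = 0.705 with an estimated correlation). Without wt clone 12 the call was lost (adjusted p = 0.072), as with genes that overlap no other gene (adjusted p = 0.123), with a range of 0.0309 to 0.705 over the alternatives. Lipid synthesis genes fell in 9 of 20 cases and rose in 1, against 12 and 1 adjusted over the list alone, with Scd1 at -0.82 ± 0.09 (adjusted p = 0.0137, and adjusted p = 0.851 with an estimated correlation). With genes that overlap no other gene the lipid list had an adjusted p of 0.0527, with a range of 0.00414 to 0.851 over the alternatives. Mitochondrial transcripts rose in 6 of 13 cases, also when adjusted over the list alone, with mt-Nd1 at 0.55 ± 0.06 (adjusted p = 0.00765, and adjusted p = 0.734 with an estimated correlation). Without E518K clone 8 that call was lost (adjusted p = 0.129), as with genes that overlap no other gene (adjusted p = 0.083), with a range of 2.88e-04 to 0.734 over the alternatives.

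Between E518K and wt, 3917 of 16498 genes passed the edgeR test, 1862 higher and 2055 lower in E518K, and 1095 changed at least 2-fold. The share of calls that were higher was 47.5%, against 37.5% with upper-quartile factors and 32% with limma on log2(TPM + 1). The libraries of the groups did not overlap for 62.0% of genes. Chance gives 33.3% for 4 libraries with a like spread, which is no reference here. The common biological coefficient of variation was 20.5% in wt and 9.19% in E518K. The count was 644 without E518K clone 15, 1650 without E518K clone 8, 6987 without wt clone 16, 1908 without KO library 1 and 1907 without KO library 3. Of 69 named genes that passed, 38 lost the call without E518K clone 15, 22 without E518K clone 8, 15 without KO library 1, 15 without KO library 3 and 3 without wt clone 12.

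Published miR-290 targets were lower in E518K than in KO, and Lin28a was higher. Lin28a rose by 6.41 ± 0.24 to 102.3 ± 16.6 CPM (SD, n = 2). Tgfbr2 (-4.08 ± 0.25), Irf2 (-3.68 ± 0.23), Rbl2 (-2.38 ± 0.12), Lats2 (-2.10 ± 0.10) and Casp2 (-1.62 ± 0.09) fell. Of 19 members of the list, 15 fell and 1 rose, also when adjusted over the list alone (adjusted p = 1.11e-05, and adjusted p = 0.705 with an estimated correlation). Targets of p53 fell in 15 of 21 cases and rose in 2, against 16 and 2 adjusted over the list alone, with Btg2 at -2.13 ± 0.12 and Cdkn1a at -2.09 ± 0.13 (adjusted p = 2.56e-04, and adjusted p = 0.851 with an estimated correlation).

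Glycolysis genes were higher in E518K than in KO, with Bnip3 at 1.91 ± 0.16, Aldoa at 1.81 ± 0.10 and Pkm at 1.07 ± 0.07. Of 20 members, 17 rose and 2 fell, against 17 and 3 adjusted over the list alone (adjusted p = 2.3e-04, and adjusted p = 0.851 with an estimated correlation). Ribosomal protein genes rose in 21 of 24 cases and fell in 1, also when adjusted over the list alone, with Rplp0 at 0.74 ± 0.07 (adjusted p = 1.1e-05, and adjusted p = 0.851 with an estimated correlation). Stress response genes rose in 13 of 20 cases and fell in 3, against 14 and 3 adjusted over the list alone, with Chac1 at 2.77 ± 0.14 (adjusted p = 0.00382, and adjusted p = 0.705 with an estimated correlation). Lipid synthesis genes rose in 11 cases and fell in 2, also when adjusted over the list alone, with Scd1 at 1.02 ± 0.09 (adjusted p = 0.0265, and adjusted p = 0.851 with an estimated correlation).

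Mitochondrial transcripts were lower in E518K than in KO in 8 of 13 cases, against 10 adjusted over the list alone, with mt-Co3 at -0.52 ± 0.06 (adjusted p = 0.0124, and adjusted p = 0.734 with an estimated correlation). The call was lost without E518K clone 15 (adjusted p = 0.0548) and with genes that overlap no other gene (adjusted p = 0.164), with a range of 0.00291 to 0.734 over the alternatives. Interferon and RNA sensing genes fell in 11 of 24 cases and rose in 1, also when adjusted over the list alone, but the list did not pass (adjusted p = 0.0844). Without E518K clone 8 it passed (adjusted p = 0.0458), with a range of 0.0458 to 0.734 over the alternatives. Ifi35 fell by 1.31 ± 0.12, whereas Bst2 rose by 1.01 ± 0.15. Nlrp12 span counts fell by 0.98 ± 0.07. Dnmt3l rose by 3.86 ± 0.22 and Slc16a3 by 4.16 ± 0.26, both to levels below those in wt.

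In total 6902 genes passed the edgeR test between E518K and KO, 3636 higher and 3266 lower in E518K, and 1718 changed at least 2-fold. The libraries of the groups did not overlap for 80.5% of genes. Chance gives 33.3% for independent libraries with a like spread, which is no reference here. Both KO titles carry the same clone number, and the common biological coefficient of variation was 2.61% in KO and 9.19% in E518K. Without KO library 1 the count was 3285, without KO library 3 it was 3306 and without E518K clone 8 it was 4042. Of 71 named genes that passed, 11 lost the call without KO library 1, 11 without KO library 3, 8 without E518K clone 8 and 6 without E518K clone 15.

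Genes with a seed site for 7 of 15 miRNA families shifted upward in KO at the preset correlation, and with an estimated correlation 0 of the 7 passed (adjusted p from 0.482 to 0.531). The 2498 genes with a miR-290 site changed by 0.29 more on the log2 scale than the 12461 genes without (camera adjusted p = 0.00387), and the 2065 genes with a miR-17 site by 0.32 more (adjusted p = 9.2e-04). Sites of miR-25, miR-26, miR-21, miR-130 and miR-182 also passed, with differences of 0.29, 0.25, 0.23, 0.25 and 0.24. Sites of miR-290 and miR-17 share 6 bases. In adjustments chosen after seeing the data, their differences were 0.16 and 0.20 after UTR length, UTR GC content and expression, and 0.11 and 0.14 with all families fitted together as well. Sites of let-7, miR-15, miR-183 and miR-34 and of the controls miR-1, miR-9, miR-122 and miR-124 did not pass in KO against wt. The differences of these controls were also upward, at 0.17, 0.17, 0.06 and 0.13 in the same order. Between E518K and wt, 0 of 15 families passed in limma and 0 had an unadjusted p under 0.05, with a miR-290 difference of 0.04 (adjusted p = 0.633) that was -0.0038 without wt clone 12.

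Between E518K and KO, the log2 fold change of genes with a miR-290 site differed from that of the others by -0.25 (adjusted p = 9.2e-04), and 8 of 15 families passed, the control miR-9 among them (adjusted p = 0.027). None of these passed with an estimated correlation, where 0 of the 45 seed tests did. After UTR length, UTR GC content and expression the miR-290 difference was -0.15 in E518K against KO, and in KO against wt those of miR-25, miR-130, miR-182, miR-26 and miR-21 were 0.12, 0.10, 0.09, 0.03 and -0.01. After the same adjustment the controls miR-124, miR-9, miR-1 and miR-122 stood at 0.06, 0.05, 0.04 and 0.01 in KO against wt. The families miR-26 and miR-21 were therefore not set apart from the controls. With 8mer sites only, the miR-290 difference was 0.47 in KO against wt and -0.40 in E518K against KO (adjusted p = 2.89e-05 and 3.69e-06).

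**Figure D3:**
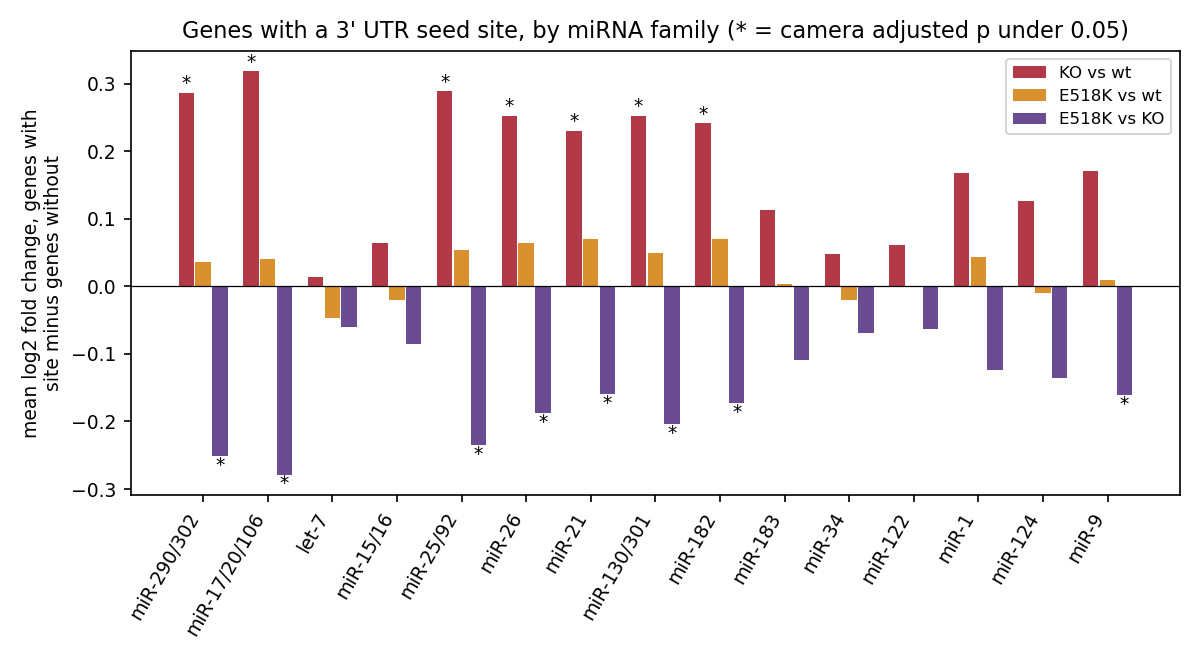
Difference in mean log2 fold change between genes with and without a 3′ UTR seed site for each miRNA family, with bars coloured by comparison. An asterisk marks a camera adjusted p under 0.05; no family has one in E518K against wt, and miR-17 stands at 0.32 in KO against wt and -0.28 in E518K against KO.

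On a scale from wt at 0% to KO at 100%, the published miR-290 targets of E518K lay at 5.1%, with a range of 0.95% to 9.07% over choices of single clones. Genes with a miR-290 site lay at 13.7%, with a range of -6.03% to 29.3%, and those with an 8mer site at 16.6%, with a range of 3.52% to 27.7%. These values come from 2 libraries per group and have no test. The position of the genes with a site was 1.24% without wt clone 12, 23.1% without wt clone 16 and 6.6% without E518K clone 15, and that of the published targets 8.02% without wt clone 12 and 2.24% without wt clone 16. With log2(TPM + 1) the published targets lay at -1.9%.

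The changes of KO and E518K against wt overlapped. In both, 1368 genes were higher and 1501 lower, and 197 genes were called in opposite directions. Calls independent between the comparisons would give 510.8 genes higher and 610.7 lower in both. That reference does not hold here, because both comparisons used the same wt libraries. Simulated unchanged groups sharing those libraries had 0 calls in either comparison and give no reference for these counts. Of the genes called in KO, 30.4% were called in the same direction in E518K, 2.09% in the opposite direction and 67.5% were not called. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.718 and a covariance of 0.585. Simulated unchanged groups gave 0.508 and 0.0496 with 1 spread for all groups, and 0.772 and 0.0969 with the spread of each group, chosen after seeing the data. The value of r therefore did not exceed what random scatter of the shared wt libraries can give, whereas the covariance did. The simulations held no shift common to both wt clones. They cannot tell such a shift apart from a change shared by KO and E518K. With the wt clones split between the comparisons, so that no wt library was shared, r was 0.476 and 0.56. Scatter of single wt clones is not shared in that split, so these values argue against it as the whole source of r. A shift common to both wt clones stays possible. The overlap in direction without E518K clone 15 was 572 genes, without E518K clone 8 it was 1375, without wt clone 16 it was 5407, and without KO library 1 or 3 it was 1372 or 1340.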

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

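Apart from the summing of the KO libraries and the restriction to genes that overlap no other gene, no test in this part was chosen only after the result was seen. A rule fixed beforehand named the members of the gene lists that were called on opposite sides of wt in KO and in E518K. Of 609 list members tested, 13 were. A gap between E518K and KO follows from this choice, so its size is given below without being taken as support.

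Jun and Myc, which encode immediate early transcription factors, had the widest gaps. Jun was higher than wt in KO (2.32) and lower in E518K (-0.58), a difference of -2.89 between E518K and KO. Myc was lower in KO (-1.76) and higher in E518K (0.72), a difference of 2.48. Anxa2 differed by -2.31, the imprinted gene Plagl1 by -1.95, the collagen gene Col4a2 by -1.78, the kidney development gene Eya1 by -0.93, the lysosomal gene Grn by -0.73 and the pluripotency factor gene Tfcp2l1 by -0.55, each above wt in KO and below it in E518K. The imprinted gene Snrpn differed by 1.43, the pluripotency genes Utf1, Nr0b1 and Zfp42 by 1.05, 0.73 and 0.46, and Tarbp2, a partner of Dicer, by 0.64, each below wt in KO and above it in E518K.

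No gene changed sides without any 1 library or in the other alternatives that tested it. The restriction to genes that overlap no other gene tested 10 of the 13, and limma on log2(TPM + 1) tested 11. Without 1 library, E518K against wt ranged from -0.74 to -0.39 for Jun and from 0.60 to 0.84 for Myc, but calls were lost. In E518K against wt, 13 of the 13 calls were lost without E518K clone 15, 10 without clone 8, 7 without KO library 1, 7 without KO library 3 and 1 without wt clone 12. In KO against wt, 5 were lost without KO library 1, 6 without KO library 3 and 1 without wt clone 16, E518K clone 8 or E518K clone 15. With the KO libraries summed, an alternative chosen after seeing the data, 7 of the 13 calls were lost in KO against wt and 7 in E518K against wt. In E518K against wt, 7 were lost with only the 4 libraries compared, 4 of the 11 tested with limma on log2(TPM + 1), and 1 each with DESeq2, no low-count filter and upper-quartile factors. In KO against wt, 2 were lost with upper-quartile factors and 1 with no low-count filter. No explanation was tested for these genes.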

How the results depend on the processing

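Summing the KO libraries, keeping only genes that overlap no other gene, adjusting for UTR composition, fitting the seed families together and simulating each group with its own spread were tests chosen only after the results were seen. The cause of a change was not tested unless stated. No paired analysis was possible because the groups share no replicate numbers. Fits without 1 library left 1 library in a group, which is assumed to vary like the other groups.

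Counts of called genes held within 1.5 times under RLE and upper-quartile factors, other low-count filters, DESeq2 and limma on log2(TPM + 1). With only the 4 libraries compared, E518K against wt had 1999 calls. Summing the KO libraries gave 6163, 1909 and 3267 calls for KO against wt, E518K against wt and E518K against KO, with fewer libraries. A 2-fold minimum gave 3560, 1095 and 1718. Without 1 library the counts ranged from 6084 to 10958, 644 to 6987 and 3285 to 9482, and the overlap from 572 to 5407. The correlation between the changes of KO and E518K against wt was 0.718, against 0.508 in simulated unchanged groups with 1 spread and 0.772 with the spread of each group. The lowest values came without KO library 3, E518K clone 15, KO library 1 and E518K clone 15, and the highest for E518K against wt and for the overlap without wt clone 16.

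Of 102 list tests, 22 passed and 0 with an estimated correlation. With fry, which tests a list against no change, 40 passed. The direction of published miR-290 targets and p53 targets in E518K against wt, neither past the threshold, reversed with fry (adjusted p = 0.514 and 0.98), and that of published targets with genes that overlap no other gene (adjusted p = 0.909). Without 1 library the adjusted p of uncalled lists whose direction changed ranged from 0.782 to 0.97 for published targets, 0.206 to 0.886 for p53 targets and 0.443 to 0.934 for ribosomal proteins in E518K against wt, and from 0.655 to 0.983 for the lysosome list in KO against wt.

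Of 45 seed tests, 15 passed and 0 with an estimated correlation, where the miR-290 differences of 0.29 and -0.25 no longer passed in KO against wt and E518K against KO. Adjusted for UTR length, GC content and expression they were 0.16 and -0.15, and with all families fitted together as well 0.11 and -0.0992. With 8mer sites only they were 0.47 and -0.40, with 18 calls, and among genes with an average log2 CPM of at least 3 they were 0.33 and -0.29, also with 18 calls. In E518K against wt the difference ranged from -0.0038 to 0.0623 without 1 library. With log2(TPM + 1) the position of the published targets was -1.9%.

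Among named genes, no value past the threshold changed direction. With the KO libraries summed, 10 of 80 calls were lost in KO against wt, 15 of 69 in E518K against wt and 10 of 71 in E518K against KO, and with only the 4 libraries compared 1, 16 and 0. Uncalled values did so in E518K against wt for Lin28a with upper-quartile factors (-0.0091) and log2(TPM + 1) (-0.0101) and for Ago3 with log2(TPM + 1) (-0.0038). In E518K against KO they did so for Hspa5 (-0.0017) and Laptm5 (-0.0744) with log2(TPM + 1), and for Cd3e (0.0044) and Krt18 (0.0129) with genes that overlap no other gene. Without 1 library the range crossed 0 in E518K against wt for Dgcr8 (-0.67 to 1.67), Lin28a (-0.19 to 0.31), Ago3 (-0.0902 to 0.203) and Btg2 (-0.22 to 0.13), in KO against wt for Gdf15 (-0.0799 to 0.379) and Psap (-0.0272 to 0.267), and in E518K against KO for Cd3e (-0.0748 to 0.0564) and Krt18 (-0.12 to 0.11).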

Other observations

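Several developmental genes outside the lists described above differed from wt in both KO and E518K. The neurofilament genes Nefl and Nefm were higher in KO (2.58 and 2.45) and in E518K (2.33 and 2.20), although the neural list did not pass (camera adjusted p = 0.407 and 0.437). The Wnt feedback genes Notum and Sp5 were higher in KO (2.84 and 2.41) and in E518K (1.66 and 1.47), and the Wnt list did not pass (adjusted p = 0.0844 in both). Kdr, a receptor for VEGF, was higher in KO (4.56) and E518K (2.83), while the imprinted genes Phlda2 and Peg10 were lower in KO (-3.49 and -2.53) and E518K (-2.12 and -1.68). The imprinted list did not pass (adjusted p = 0.431 and 0.14), and its members moved both ways, with 4 higher and 8 lower in KO. Among genes of kidney development, Mycn was higher in KO (1.15) and E518K (0.89), and that list did not pass (adjusted p = 0.76 and 0.615).

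Of the tests below, those on the shift of the wt libraries, on either wt clone, on the vector and on immune cells were chosen only after the result was seen. The bounds were also tightened later: a spread was added for the GC content correction and the immune markers, and a call with an estimated correlation for the vector, set after that value was known.

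The Nlrp12 span counts rose in KO by 4.85. A general rise of genes with a like span and wt level was argued against by the median KO change of 0.048 among 1338 such genes. Their 99th percentile was 2.05. Nlrp12 was named for its large change, so its place above that percentile follows from the choice and is no support. Reads running in from neighbours cannot be told apart from a rise within the span. The nearest tested gene, Myadm at 39340 bp, changed by -0.45, but no tested gene with coordinates lies on the other side. A candidate explanation is that unprocessed primary transcripts of the miR-290 cluster were counted over this span. Only 4 other low-count genes held hairpins of the tested families, too few to decide, and their median of 0.53 lay at percentile 80.6 of random matched sets.

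Hypoxia and glycolysis genes were lower in KO and E518K than in wt, and 15 of the 17 that fell in KO also fell in E518K. A shift of the wt libraries as the whole cause of both changes was argued against by the median of 0.69 in E518K against KO. That comparison holds no wt library, so a wt shift behind the E518K change and part of the KO change stays possible. A cause in 1 unusual wt clone was argued against by the E518K against wt median, which stayed at -0.84 or lower without either clone. Bias by GC content, span or expression was argued against as the whole cause, as the KO median was -1.38 after a linear correction (bootstrap SD 0.31, 19 members) and -1.64 before. Culture density and harvest, which may differ between lines, were not tested.

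Interferon and RNA sensing genes were higher in KO and E518K than in wt, and 7 of the 13 that rose in KO also rose in E518K. Absence of the vector in KO cannot be told apart from other causes of the KO change. It cannot be the cause of the E518K change, because E518K and wt both carry a vector. The camera call between E518K and wt (adjusted p = 0.00965, with a range of 0.00233 to 0.705 over the alternatives) is part of the pattern itself. It was not kept with an estimated correlation (adjusted p = 0.705). Immune cells in the cultures cannot be told apart from a change in the stem cells, because the 8 tested markers moved both ways (SD 1.14). Cd3e was higher in KO and E518K than in wt, whereas Itgam and Cd79a were lower in both. A further 4 markers were too low to test, which does not point to immune cells. The higher of the marker medians was 0.0124, and the most abundant marker, Laptm5, had 277.5 CPM in KO and 299.1 CPM in wt.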
